A study of Arabidopsis thaliana with 4 samples.

How the data were processed

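The series holds chromatin immunoprecipitation sequencing (ChIP-seq) of phytochrome A in Arabidopsis thaliana. Phytochrome A (phyA) is the plant photoreceptor for far-red light and enters the nucleus after irradiation. Per the labels' protocols, etiolated seedlings aged 4 days carried a phyA-GFP fusion under the PHYA promoter in the phyA201 mutant and received 3 h of far-red light. In those protocols 5 g of seedlings were cross-linked with 1% formaldehyde, and sonicated chromatin was precipitated with an anti-GFP antibody. The 3 ChIP samples are given as biologically distinct replicates, and 1 input sample (DNA before precipitation) belongs to the series. No processed file of the input was used here, so every comparison below rests on the 3 ChIP peak lists.

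Per the submitters' processing notes, reads were aligned with Bowtie and the genome build was TAIR10. The peak caller, its settings and its filters are not given in the sources used here. Each replicate has its own peak list of 9 unnamed columns, and whether the input entered the calling is not given either. The meaning of the columns was read from the values and from the column order, which is that of the table written by MACS 1.4. In every line of each list the length column equalled end minus start plus 1, so starts were read as 1-based. The authors' deposited read counts per peak are whole numbers and were not normalized. The deposited score rises with peak strength and was read as minus 10 times the log10 of a p-value. The deposited fold enrichment is a linear ratio, read as ChIP signal at the summit over the caller's local background, and was never below 2.95 in any of the 3 lists. The last deposited column was read as a false discovery rate in percent and never exceeded 4.99, 4.98 and 4.99% in replicates 1, 2 and 3. Those shared limits are values of the lists, and which filters were applied is not stated. Fold enrichment served as the per-peak value: to describe and rank peaks within a list, to describe regions by their mean and SD over the 3 lists, and to correlate the lists across regions. Values of separate lists need not share a scale, so these SDs hold differences between the lists as well as between samples. Library totals are not given in the sources used here, so sequencing depth is unknown beyond the reads inside peaks.

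Peaks of the 3 replicates were merged where they overlapped by at least 1 bp. A merged region with a peak from all 3 replicates is called a shared region, and its position is the midpoint of the merged interval. Where a replicate had several peaks in a region, the one with the highest fold enrichment was used. Gene names came from the NCBI gene table of assembly TAIR10.1, whose nuclear chromosomes carry the TAIR10 coordinates. That match was checked on the peaks. In replicate 1, 35.1% of summits lay inside protein-coding genes, against 63.7, 62.4 and 64.7% after adding 2000, 5000 and 10000 bp to every summit. The table gives 27444 protein-coding genes and 10455 other genes on the 5 nuclear chromosomes. It gives no strand, and no genome sequence was used here. The planned promoter (upstream of the transcription start) was therefore replaced by the flank, the 1000 bp outside either end of a protein-coding gene. Distance to a transcription start was replaced by distance to the nearest end of a protein-coding gene. Promoters and downstream regions are not told apart, exons, introns and UTRs are not separated, and the planned motif tests were not run. Runs of unknown bases were not excluded from random placements.

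Overlap between replicates was tested against 10000 random placements of the second replicate's peaks on the same chromosome (one-sided permutation p, adjusted by the Benjamini-Hochberg method over the 6 ordered pairs). The number of shared regions was compared with 1000 random sets of all 3 lists. Locations of shared regions were compared with 10000 random placements (two-sided permutation p, adjusted over 4 classes). Each midpoint took the first class that held it, in the order protein-coding gene body, flank, other gene and rest. A gene counted as having a shared region when the region overlapped 1 of its flanks by at least 1 bp. Gene lists were compared with all other protein-coding genes by Fisher's exact test (two-sided, adjusted over the 15 lists). Of 414 list members, 409 matched the gene table by identifier and name, and 5 were left out. The 5 were FED2 of the photosynthesis list and the EF1A genes of the housekeeping list, which left 17 housekeeping genes. The tests treat genes and regions as independent, which neighbouring ones are not. Intervals of shares are 95% Wilson intervals and cover counting error only. Random placements for the alternatives numbered 1000, and matched random lists 10000.

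Groups, tests, gene lists, alternatives and the rule for named genes were set before the data were examined. The rule named the 15 genes whose shared region had the highest mean percentile rank of fold enrichment, each region naming the gene whose end is nearest to its midpoint. It also named up to 4 members of each list with a shared region, ranked in the same way, and PHYA, FHY1, FHL, HY5, PIF3, CHS and PORA whatever their values. Not every gene that the rule named is reported here. The alternatives were a stricter peak set (the 50% of peaks with the highest fold enrichment), a reciprocal overlap of 50%, regions in at least 2 of the 3 replicates, leaving out each replicate, flanks of 500 and 2000 bp, flanks taken before gene bodies, peaks or regions moved by 5000 to 20000 bp in place of random placement, and random lists matched on the length of neighbouring intergenic sequence in 10 bins. On simulated data, a planted overlap of 28.2% of 7084 peaks was recovered as 28.5%. Among simulated lists of 30 genes, the list test called 80.4% of those with a planted odds ratio of 3 and 2.6% of those with none. That simulation drew hits independently for each gene, at a share above the observed one, and called lists without adjustment. Its shares therefore do not give the power or the error rate of the lists tested here. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and figures used matplotlib 3.10.9.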

Results

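Binding of phyA to chromatin was profiled in 3 ChIP samples of seedlings that had received far-red light. The lists held 7084, 7534 and 6037 peaks in replicates 1, 2 and 3 (mean 6885 ± 768, SD, n = 3). The peaks contained 11110782, 7702516 and 4951883 reads and covered 12.4, 10.4 and 7.93 Mb. Replicate 1 had the longest peaks, with a median of 1477 bp against 1168 and 1117 bp in replicates 2 and 3. Median fold enrichment was 4.38, 3.85 and 3.58. Peak counts, lengths and fold enrichments of different replicates were not compared by a test, because library depth is unknown and may set all of them.

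The first comparison asked how far the replicates named the same places in the genome. Of the peaks of replicate 1, 72.4% overlapped a peak of replicate 2, against 17.8% ± 0.44 (SD) with random placement. The other ordered pairs gave 55.9 to 71.5% against 12.7 to 16.9% at random. In each of the 6 pairs the ratio to chance lay between 4.01 and 4.50, with an adjusted permutation p of 0.0001, the smallest that 10000 placements can give. Merging gave 10015 regions, of which 3323 (33.2%) held peaks of all 3 replicates, 2667 held peaks of 2 and 4025 of 1 only. Random placement of the 3 lists gave 255 ± 15.7 such shared regions (SD over 1000 sets), so that the observed number was 13.1 times the chance level (one-sided permutation p = 0.001, the smallest possible).

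Within the shared regions, summits of different replicates lay close together. The median distance between summits was 77, 85 and 83 bp for replicates 1 and 2, 1 and 3, and 2 and 3. Summits placed at random within the same regions would lie a median of 593 bp apart. In some regions the summits of different replicates lay far apart, and the mean fold enrichment there may join different sites. The order of the regions by fold enrichment gave a Spearman correlation across the 3323 regions of 0.39, 0.32 and 0.32 for those pairs and a Pearson correlation of log2 fold enrichment of 0.45, 0.39 and 0.40. Without the 4 most enriched regions the Pearson correlations were 0.41, 0.34 and 0.34, and the Spearman correlations stayed at 0.39, 0.32 and 0.32. These are correlations across regions, which are not independent replicates. With the peaks of each replicate put into 4 equal classes of fold enrichment, 74.8% of the highest class lay in shared regions in replicate 1, against 31.0% of the lowest class. The same shares were 74.5 and 31.1% in replicate 2 and 80.6 and 47.8% in replicate 3.

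The second comparison, after the study's interest in promoters, was where the shared regions lay. Summits were concentrated at the ends of genes. In replicates 1, 2 and 3, 70.0, 70.4 and 65.8% of summits lay within 500 bp of an end of a protein-coding gene, against 35.4% ± 0.32 (SD) with random placement. The fullest 100 bp bin was the one just outside the gene, with 17.6, 17.7 and 15.6% of summits against 3.57% at random. Of the 3323 shared regions, 1360 (40.9%) had their midpoint in a flank, against 20.4% ± 0.70 at random, a ratio of 2.01. Of the midpoints, 59.8% lay within 500 bp of a gene end, against 35.4% ± 0.82. Midpoints were fewer than chance inside protein-coding genes (44.5% against 54.2% ± 0.87) and in other genes, which include pseudogenes (1.53% against 8.61% ± 0.49). The remaining 13.1% lay elsewhere, against 16.8% ± 0.65. Each class differed from chance with an adjusted permutation p of 0.0002, the smallest that the placements can give. Against regions moved by 5000 to 20000 bp, which keep their surroundings, other genes held 1.53% against 2.25%, and the direction of the remaining class turned, with 13.1% against 10.9%. The remaining class also did not differ detectably from chance with the stricter peak set (ratio 0.89) or with flanks of 500 bp (ratio 1.03). Because the gene table gives no strand, the flank classes include sequence downstream of genes as well as promoters.

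**Figure D1:**
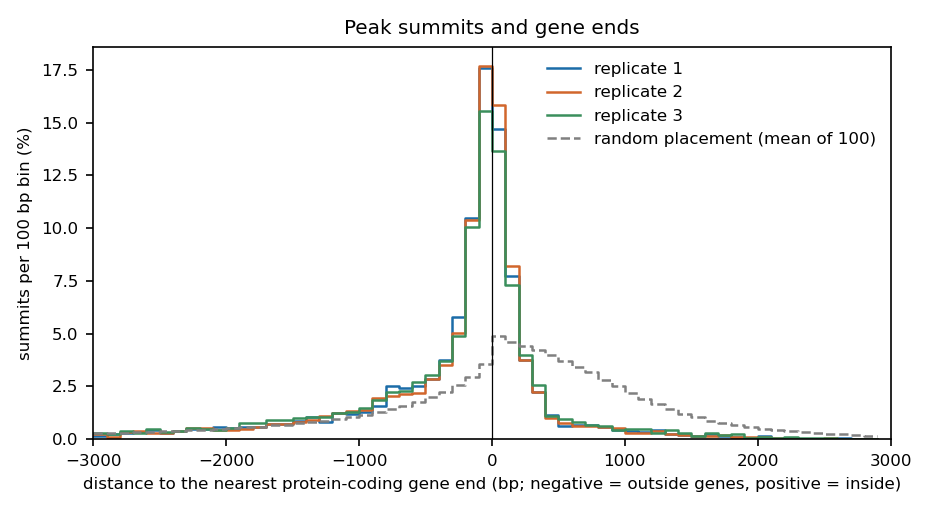
Distance from each peak summit to the nearest end of a protein-coding gene (bp, negative outside genes and positive inside), as the percentage of summits per 100 bp bin, for the 3 replicates (coloured lines) and for random placement (dashed line, mean of 100 placements). In all 3 replicates the fullest bin is the 100 bp just outside the gene end, with 15.6 to 17.7% of summits against 3.57% at random.

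The third comparison asked which genes had shared regions beside them. A shared region overlapped a flank of 5524 of 27444 protein-coding genes (20.1%), against 4335 ± 59.5 genes for regions placed at random (two-sided permutation p = 0.002, the smallest possible). Random placement also reaches gene-poor parts of the chromosomes, where shared regions were rarer. The excess may in part reflect that, and moved regions were not used for this count. The 5524 genes shared 3067 regions that touched a flank, which is 1.80 genes per region, so that a region often could not be tied to a single gene. Taking only the gene nearest to the midpoint gave 2936 genes, and requiring a summit of every replicate in the gene's flanks gave 2399. The latter count took the summits of any peaks in either flank. A gene counted in that way need not be among the 5524 with a shared region.

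The 4 most enriched loci had mean fold enrichments of 17.9 to 29.1, against 9.08 for the next one. The region of UVR8 (AT5G63860), the UV-B photoreceptor gene, lay on chromosome 5 from 25553606 to 25559524 (TAIR10) with a fold enrichment of 29.1 ± 5.29 (SD, n = 3). Its summits lay apart, at 25556444 in replicate 1 and at 25558206 and 25558195 in replicates 2 and 3. A region on chromosome 1 from 18656601 to 18659171 reached 24.6 ± 4.42. It covers the sequence between 2 genes and an end of each, VIIIA (AT1G50360), a myosin gene, and FYPP1 (AT1G50370), which encodes a phytochrome-associated protein phosphatase, and its summits were inside VIIIA. The region at DET1 (AT4G10180), a repressor of light responses, lay on chromosome 4 from 6348019 to 6349465 and had 18.0 ± 7.63. The region of FHY1 (AT2G37678), whose product carries phyA into the nucleus, lay on chromosome 2 from 15800525 to 15803838 and had 17.9 ± 9.36. All 12 summits of these 4 regions lay inside protein-coding genes. Their fold enrichment had a median SD between replicates of 0.48 on the centred log2 scale, against 0.19 for the next 100 regions. The SD was 0.25 at UVR8, 0.39 at the region of VIIIA and FYPP1, 0.57 at DET1 and 0.70 at FHY1. The next region, on chromosome 5 from 3590147 to 3595456, had 9.08 ± 2.21. It spans HY5 (AT5G11260), the transcription factor that promotes seedling development in light, and reaches the neighbouring AT5G11250, and its summits lay in HY5.

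**Figure D2:**
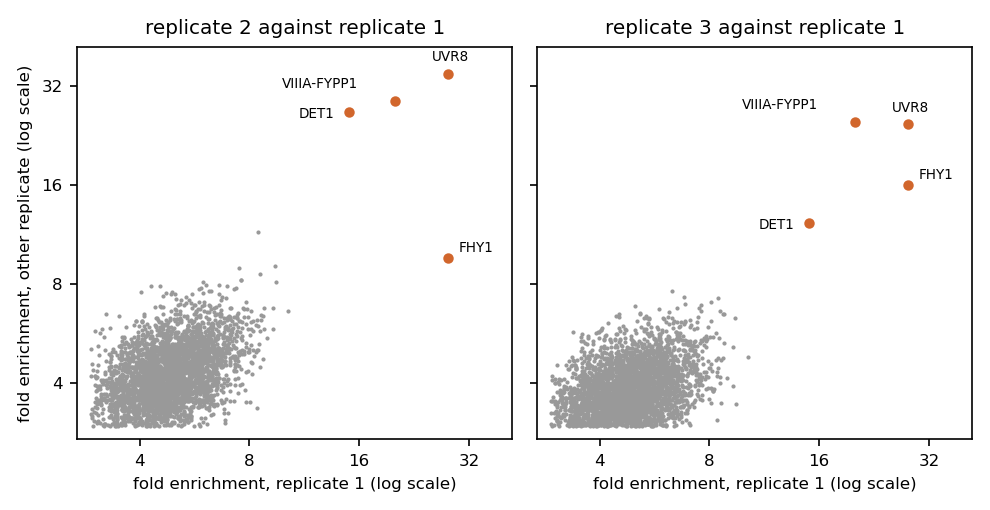
Fold enrichment of the 3323 shared regions in replicate 2 (left) and replicate 3 (right) against replicate 1, on log axes. Each point is a region, and the 4 most enriched regions are coloured and named by gene. FHY1 had 28.0-fold enrichment in replicate 1 and 9.56 and 16 in replicates 2 and 3.

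The remaining regions at the top of the ranking had fold enrichments from 6.63 to 8.26. Among their genes was GAE1 (AT4G30440), of pectin precursor synthesis, with 7.36 ± 1.26 (SD, n = 3). The transcription factor gene WRKY47 (AT4G01720) had 7.73 ± 1.1, and PYL5 (AT5G05440), of the abscisic acid receptor family, had 7.25 ± 0.76. EXL2 (AT5G64260) had 6.69 ± 0.45, with summits that lay apart, at 25705324, 25702761 and 25705150 in replicates 1, 2 and 3. Also among the first 15 genes were AT4G01245, AT3G52500, AT4G24410, AT5G39890 and AT5G21090, which carry no symbol in the gene table.

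Genes of light signalling carried shared regions more often than other genes. Of 44 photoreceptor and light signalling genes, 23 (52.3%, 95% interval 37.9 to 66.2%) had a shared region in a flank, against 20.1% of other genes (odds ratio 4.36, Fisher's exact test, adjusted p = 1.1e-05). The highest ranks were those of UVR8, FHY1, DET1 and HY5. The 23 genes also included, at lower ranks, PIF3, whose product is a phytochrome-interacting factor that acts in darkness, at 4.75 ± 1.54-fold enrichment (SD, n = 3, as for the values of list members that follow), and FHL, the homologue of FHY1, at 4.58 ± 0.48. The PIF3 relatives PIF1 (3.69 ± 0.13), PIF4 (4.22 ± 0.85), PIF5 (6.41 ± 1.79) and PIF6 (4.99 ± 0.42) had shared regions and PIF7 did not. Of the phytochrome genes, PHYB (3.81 ± 0.48) had one, and PHYA, PHYC, PHYD and PHYE did not. The PIF3 relatives and the phytochrome genes other than PHYA were chosen after their values were seen. With a summit of every replicate required in the flank, 9 of the 44 genes were counted and the odds ratio was 2.69. In the flanks of PHYA itself, replicates 1 and 2 each had 1 peak and replicate 3 had 0. The plants also carry the PHYA promoter in the phyA-GFP fusion, so reads there need not come from the PHYA gene itself.

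Photosynthesis genes also had shared regions more often than other genes. Of 49, 30 (61.2%, interval 47.2 to 73.6%) had a shared region, with an odds ratio of 6.29 and an adjusted p of 5.8e-09 by Fisher's exact test. The highest ranks were those of RBCS1A, of the Rubisco small subunit (5.51 ± 0.77-fold), PSBO1 of photosystem II (5.17 ± 0.82), LHCA2 (5.01 ± 1.02) and LHCB4.1 (5.10 ± 1.25) of the light-harvesting complexes. The 30 genes lay at 27 distinct regions. With the stricter peak set, 9 of the 49 genes had a shared region and the odds ratio was 2.7. The RBCS and LHCB1 genes are near-identical copies, between which the authors' alignment could split reads. Chlorophyll, haem and carotenoid genes did not pass the test, with 8 of 22 (36.4%, adjusted p = 0.081 by Fisher's exact test). They passed it without replicate 1 (odds ratio 3.64) and without replicate 3 (3.83), against 2.27 with all replicates. Among them, HEMA2, of the first step of tetrapyrrole synthesis, had 5.39 ± 0.66, PSY, of carotenoid synthesis, had 4.98 ± 1.24, and the protochlorophyllide reductase genes PORB and PORA had 4.40 ± 0.95 and 4.32 ± 0.36. Flavonoid and phenylpropanoid genes did not pass either, with 7 of 25 (28.0%, adjusted p = 0.37 by Fisher's exact test). CHS, the entry enzyme of flavonoid synthesis, had 3.56 ± 0.49, and 4CL1, C4H, PAL2 and F3H had 5.58 ± 1.76, 4.48 ± 1.04, 4.32 ± 0.48 and 4.26 ± 0.93. In replicate 3, CHS had a value of 3, near the lowest value of the lists (2.95).

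Hormone lists differed in their calls. Abscisic acid genes (12 of 21, 57.1%, adjusted p = 0.00051), brassinosteroid genes (11 of 20, 55.0%, adjusted p = 0.0011), jasmonate, salicylate and defence genes (15 of 32, 46.9%, adjusted p = 0.0011) and auxin genes (18 of 44, 40.9%, adjusted p = 0.0032) passed Fisher's exact test. Ethylene genes (8 of 22, 36.4%, adjusted p = 0.081) and gibberellin genes (6 of 23, 26.1%, adjusted p = 0.47) did not pass the same exact test. With a summit of every replicate required in the flank, the abscisic acid, brassinosteroid and jasmonate lists no longer passed, at odds ratios of 2.46, 3.49 and 2.41 against 5.30, 4.86 and 3.51. Without replicate 3 the odds ratio of the abscisic acid list was 3.53. The jasmonate list also no longer passed with the stricter peak set (2.22). The ethylene list passed without replicate 3, at an odds ratio of 2.65 against 2.27. The gibberellin list, at 1.4, passed with the nearest gene only (2.95) and turned to 0.99 with a summit of every replicate required in the flank. Whether the hormone lists differed from each other was not tested. The abscisic acid genes included the kinase gene SNRK2.3 (6.16 ± 1.03), the phosphatase genes ABI1 (5.35 ± 0.79) and HAI1 (5.34 ± 0.63) and the transcription factor gene ABF2 (5.20 ± 0.28). Brassinosteroid genes included the receptor gene BRI1 (5.66 ± 2.26), its partner BAK1 (5.30 ± 0.91), the kinase gene BIN2 (5.49 ± 1.18) and BEE1 (5.27 ± 0.60). The auxin receptor gene TIR1 had 5.91 ± 1.04, IAA4 had 5.51 ± 1.21, and the response factor genes ARF2 and ARF19 had 5.29 ± 0.45 and 5.38 ± 0.82. The jasmonate repressor genes JAZ1, JAZ9 and JAZ5 had 5.44 ± 1.00, 5.33 ± 1.18 and 4.89 ± 1.3, and MYC2, the transcription factor gene they act on, had 4.92 ± 1.15. Among ethylene genes, ACS2 of ethylene synthesis had 5.90 ± 2.05, the signalling kinase gene CTR1 had 5.78 ± 1.37 and EBF1 had 4.67 ± 1.13. The gibberellin receptor gene GID1B had 7.20 ± 2.77, the DELLA repressor gene GAI had 4.44 ± 0.42, and GA2OX6 and GA2OX2, of gibberellin breakdown, had 4.67 ± 0.93 and 4.60 ± 1.33. Summits of the replicates lay far apart at GID1B (23288288 in replicate 1, 23285871 and 23285849 in replicates 2 and 3). So did those of GAI, GA2OX2, BEE1 and JAZ9, among others. GA2OX2 had 3.21 in replicate 3, near the lowest value of the lists (2.95).

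Stress, clock and cell wall genes passed as well. Of the heat, cold and oxidative stress genes, 16 of 25 (64.0%) had a shared region (adjusted p = 1.1e-05 by Fisher's exact test). They included the cold regulator CBF2 (5.83 ± 0.64), MBF1C (5.94 ± 1.86), the heat shock factor gene HSFA2 (5.17 ± 0.45) and ELIP1, of photoprotection (5.05 ± 0.40). With a summit of every replicate required in the flank, 3 of these 25 genes were counted and the list no longer passed (odds ratio 1.42 against 7.07). CBF2 has neighbours of related sequence, and whether reads were split among them was not tested, so its value may be uncertain. Cell wall genes reached 11 of 18 (61.1%, adjusted p = 0.0005 by Fisher's exact test, odds ratio 6.25 and 9.46 without replicate 1), among them the expansin gene EXPA1 (6.34 ± 1.60), the cellulose synthase genes CESA3 (5.88 ± 1.90) and CESA1 (5.18 ± 1.29) and XTH22 (4.83 ± 1.41). Clock and flowering time genes reached 10 of 24 (41.7%, adjusted p = 0.027 by Fisher's exact test). They included GI (5.78 ± 1.32), PRR5 (5.51 ± 1.16) and CCA1 (5.44 ± 1.83) of the clock and the flowering integrator SOC1 (5.56 ± 1.61). The clock list, with an odds ratio of 2.84, no longer passed with regions in at least 2 replicates (2.06), flanks of 2000 bp (2.17), a background of genes with a symbol (2.18) or the nearest gene only (2.2).

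Of the 2 control lists, 1 passed. It was tested without its EF1A genes, which did not match the gene table by name. Abundantly transcribed housekeeping genes had shared regions in 11 of 17 (64.7%, interval 41.3 to 82.7%, odds ratio 7.29, adjusted p = 0.0003 by Fisher's exact test). They included the actin gene ACT7 (6.66 ± 2.7), the ubiquitin gene UBQ10 (5.36 ± 1.55) and the tubulin genes TUA2 (4.92 ± 0.13) and TUA4 (5.61 ± 1.99). Actin, ubiquitin and tubulin genes have near-identical copies, between which reads could be split. The summits of these named genes lay outside the genes in every replicate, and whether copies affect the values there was not tested. Genes of other tissues (floral identity, meristem and seed storage) had them in 3 of 23 (13%, interval 4.54 to 32.1%, adjusted p = 0.60 by Fisher's exact test), namely CRB (4.26 ± 0.22), AP3 (4.43 ± 0.93) and OLEO1 (3.71 ± 0.75). OLEO1 had 3.11 in replicate 3, near the lowest value of the lists. The light signalling list did not differ detectably from the housekeeping list (odds ratio 0.60, Fisher's exact test, adjusted p = 0.63). When a summit of every replicate was required in the flank, 7 of the 17 housekeeping genes were counted. Their odds ratio against all other genes was then 7.33, and that of the light signalling list was 2.69. Those lists were not compared with each other in that setting. The list of other tissues had fewer members with a shared region than the housekeeping list (odds ratio 0.082, adjusted p = 0.026 by Fisher's exact test), and no other list differed from it after adjustment over the 14 comparisons.

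**Figure D3:**
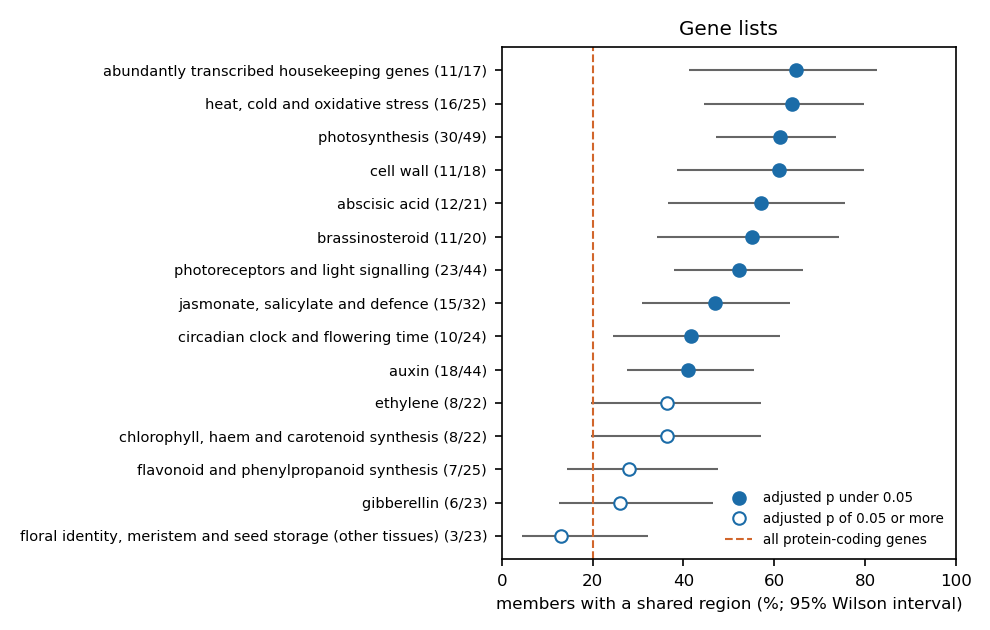
Share of each gene list with a shared region in a flank (percent, with the count of members), with 95% Wilson intervals as bars. Filled points passed Fisher's exact test after adjustment over the 15 lists, open points did not, and the dashed line marks all protein-coding genes at 20.1%. Housekeeping genes had the highest share at 64.7% and genes of other tissues the lowest at 13%.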

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

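Alternatives based on summits, on the nearest gene, on genes with a symbol, on the score and on leaving out the 4 most enriched regions were chosen after seeing the data. Of 250 values under alternatives, 224 kept their direction and their side of the threshold, or stayed within 1.5 times a count. The ratios to chance of the flank share (1.51 to 2.62, against 2.01) and of the overlap between replicates (2.91 to 12.4, against 4.01 to 4.50) stayed past their thresholds under every alternative run, as did the share within 500 bp of a gene end (1.45 to 1.84, against 1.69), with the lowest value against moved regions. The stricter peak set left 1219 shared regions and 2114 genes, and regions in at least 2 replicates numbered 5990 and gave 8975 genes, against 3323 and 5524. Leaving out 1 replicate gave 3913 to 4917 regions and 5925 to 7525 genes. A summit of every replicate in the flank gave 2399 genes, and the nearest gene only gave 2936. With the score in place of fold enrichment, the Spearman correlations were 0.59, 0.50 and 0.51. Of the 15 lists, 10 passed with all settings as planned, and 6 passed with summits in the flank. That setting ended the calls of the brassinosteroid (odds ratio 3.49), abscisic acid (2.46), jasmonate, salicylate and defence (2.41) and heat, cold and oxidative stress (1.42) lists, with fewer genes counted, and turned gibberellin to 0.99. The stricter peak set ended the call of the jasmonate, salicylate and defence list (2.22) and left no flavonoid gene (odds ratio 0). The clock list lost its call with regions in at least 2 replicates (2.06), flanks of 2000 bp (2.17), a background of genes with a symbol (2.18) and the nearest gene only (2.2). The chlorophyll list passed with regions in at least 2 replicates (4.42), and with 1 replicate left out it ranged from 2.02 to 3.83. The ethylene list ranged from 1.70 to 2.65 in the same way, and the gibberellin list passed with the nearest gene only (2.95). Where no reason is given, the cause was not tested. Without replicate 1 the cell wall list had an odds ratio of 9.46, and without replicate 3 the abscisic acid list had 3.53. Without the 4 most enriched regions the light signalling list had 3.32. Kept calls whose odds ratio moved by over 1.5 times were photosynthesis (2.7) and clock (6.01) with the stricter peak set, light signalling (2.69), photosynthesis (4.19) and cell wall (4.02) with summits in the flank, abscisic acid (3.42) with flanks of 500 bp, stress (10.8) with regions in at least 2 replicates, and auxin (5.28), jasmonate (6.52), stress (10.7) and cell wall (13.2) with the nearest gene only. Against random lists matched on intergenic length, 10 lists passed. No paired analysis was possible because only the ChIP group has numbered samples with peak lists. Planned motif tests, and with them their alternatives, were not run because no genome sequence was used here. Reads inside peaks are the only measure of depth, so a region missing from a replicate may be below that replicate's detection: the replicate with the fewest reads in peaks (4951883) had the fewest peaks (6037), but the one with the most reads (11110782) had fewer peaks (7084) than replicate 2 (7534). The alternative of regions in at least 2 replicates (5990) bears on this.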

Other observations

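The tests in this part were chosen after the result was seen, except those of the housekeeping list and of the overlap after moving peaks. Genes that do not encode proteins differed in how often shared regions overlapped them. Of 625 tRNA genes, 129 (20.6%) overlapped a shared region, against 6.92% ± 1.43 (SD) with random placement (ratio 2.98, adjusted permutation p = 0.004). The snoRNA genes (50 of 287, 17.4% against 6.97%) and lncRNA genes (516 of 3480, 14.8% against 8.10%) were also above chance, each with the same adjusted p. So were misc_RNA genes (13.6% against 8.97%) and antisense RNA genes (17.7% against 7.97%), each with an adjusted permutation p of 0.0057. The miRNA genes (24 of 326, 7.36% against 7.06%), ncRNA genes (11.8% against 9.37%) and snRNA genes (14.6% against 7.33%) did not pass, with adjusted permutation p of 0.88, 0.32 and 0.062. Pseudogenes (23 of 3917, 0.59% against 12.6%) and transcribed pseudogenes (3.24% against 9.63%) were overlapped less often than chance, each with an adjusted permutation p of 0.004. After moving the regions by 5000 to 20000 bp in place of random placement, the chance levels were 7.12% for tRNA, 9.87% for snoRNA and 9.46% for lncRNA genes and 2.64% for pseudogenes. Against moved regions the antisense RNA genes no longer passed (ratio 1.66, adjusted permutation p = 0.09) and the snRNA genes did (ratio 2.08, adjusted permutation p = 0.046). Along the chromosomes, 500000 bp bins with at least as many pseudogenes as protein-coding genes held 1.82 shared regions per Mb and 3.80 per 100 protein-coding genes, and the other bins held 32.1 and 12.4. Sequence to which reads cannot be uniquely assigned was not excluded from placements or bins. A low overlap or few regions therefore need not mean less binding.

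Genes with a symbol had a shared region more often than genes without (2561 of 10374, 24.7%, against 17.4%, odds ratio 1.56, p = 6.0e-48 by Fisher's exact test). Grouping genes by the letters of their symbol gave 84 families of at least 15 members, of which 3 passed Fisher's exact test after adjustment. These were GRF, a symbol shared by 14-3-3 proteins and growth-regulating factors (13 of 21, 61.9%, adjusted p = 0.0029), HB, of homeobox proteins (18 of 37, 48.6%, adjusted p = 0.004), and ARF, mostly auxin response factors (11 of 22, 50%, adjusted p = 0.047, all by Fisher's exact test). With a summit of every replicate required in the flank, adjusted p of the same exact test rose to 0.16, 0.72 and 0.16. The odds ratios were then 4.18, 2.02 and 4.88, against 6.46, 3.77 and 3.97, with fewer genes counted, so that of ARF did not fall.

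Among the 5 most enriched regions, 4 had every summit inside a gene of the light signalling list (UVR8, DET1, FHY1 and HY5), against 10 of all 3323 shared regions; no p-value is given because the criterion was set after the regions were seen. Whether the first 4 regions hold occupancy of the kind seen elsewhere, only stronger, was not decided, because the test was chosen after their summits were seen. Of their 12 summits, 100% lay inside genes, where random sets of 4 from the next 100 regions had an upper 95% bound of 58.3%. The evidence is mixed, since their median distance to a gene end (708 bp) was within its bound of 1626 bp, and the fifth region, at HY5, also had its summits inside the gene. A candidate explanation is extra DNA of these loci in the ChIP libraries, such as carried-over cloned or amplified DNA, which would let fold enrichment vary between samples. The median SD was 0.48 on the centred log2 scale against an upper bound of 0.32, with single regions from 0.25 (UVR8) to 0.70 (FHY1). This was also seen first, in regions picked by extreme fold enrichment from lists that need not share a scale, and so does not establish that explanation. Stronger occupancy and a binding of another kind at these genes stay open, because the input reads that could show extra copies were not analysed here.

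The lists that passed included housekeeping genes, with an odds ratio of 7.29, while genes of other tissues did not pass. This is consistent with ChIP signal at abundantly transcribed genes whatever protein is tagged. The tRNA genes, transcribed by another polymerase, overlapped shared regions 2.90 times as often as after moving the regions by 5000 to 20000 bp. That comparison was set after the excess was seen and does not decide the cause. Moved regions also lose their preference for flanks, with 40.9% of midpoints there against 22.3% after the move. Copies of tRNA genes are near-identical, and reads could be split among them. Binding of phyA to the promoters of active genes predicts the housekeeping result too and was not tested, since no sample without the tagged protein or without far-red light was analysed here.

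Replicates could share peaks because peaks crowd into the same gene-rich parts of the chromosomes. The overlap was still at least 2.91 times that after moving each peak by 5000 to 20000 bp in every ordered pair, so crowding at that scale is argued against as the whole cause. Preference for gene ends, which the moved peaks lose, stays open as a part of it.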
